A study of Mus musculus with 25 samples.

How the data were processed

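Bulk RNA-seq values were used for 6 mouse libraries, 3 control and 3 anti-CD73, from E0771 tumour preparations that the labels describe as enriched CD8+ T cells. Groups and replicate numbers came from the sample titles. The sample descriptions and the table's columns carry other numbers for the same libraries, so columns were matched by description. The other 19 samples were not analysed here. RNA was taken up in Trizol and purified with a Direct-zol kit, and libraries were made with an NEBNext Ultra II RNA kit, per the labels' protocols. Whether strand was kept is not given in the sources used here.

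The deposited signal values are gene counts that the authors divided by a DESeq size factor per library, per the labels. Bowtie 0.12.7 and the mouse build mm10 are named without a role, per the submitters' processing notes. The counter, the annotation release, the DESeq version and how reads with several matches were treated are not given in the sources used here. Reads shared between near-identical genes, pseudogenes or overlapping genes may therefore be split or lost, which makes the level of such genes uncertain. Replicates were not pooled.

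The table has 25006 entries, of which 24082 carry a symbol and 924 do not, and 18872 have a read in any library. Of the Ensembl IDs, 24942 were found in the reference name table. The table holds 0 mitochondrially encoded genes. Every value was a whole multiple of the value of 1 read in its library, so reads were recovered by division: 100% of values came out whole within 0.01 of an integer. Recovered reads ranged from 10180624 to 17161679 per library. Intervals of single read counts are exact Poisson intervals at 95% and cover counting error only.

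The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), two-sided, with no block, on the 12262 genes whose mean over the 6 libraries was at least 10. Fold changes are on this scale, which understates changes of genes with few reads. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Gene lists were tested with camera on the same fit, two-sided, with the preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 28 of 32 lists that had at least 5 tested members. The lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Since the values were not raw counts, edgeR 4.0.16 (quasi-likelihood, TMM factors) and DESeq2 1.42.0 were run on the recovered reads as alternatives. DESeq2 gave an adjusted p for 11675 genes, and genes without one were not counted as calls.

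The genes named by rule were the 12 largest changes in each direction past the threshold with groups that did not overlap. As none passed, they were the 8 smallest p in each direction, reported as not past the threshold. Predicted genes, pseudogenes, and immunoglobulin or T cell receptor variable segments were not chosen. A fixed panel of 24 genes of the adenosine pathway, T cells and ferroptosis was reported whatever its values, as were the members of each list with the smallest p. Coordinates are 1-based and come from the GRCm38.p6 RefSeq gene table, the assembly of mm10, matched by symbol.

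Other settings tried were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, TMM scaling, quantile normalization, robust empirical Bayes, replicate blocks by title number and by description number, and each library left out in turn. Alternatives chosen after seeing the data were edgeR and DESeq2 with libraries left out, the estimated correlation without control replicate 1, the removal of erythroid and haemoglobin genes with rescaling and, for the gene lists alone, a pseudocount of 0.5, a mean of at least 50, quantile normalization, robust empirical Bayes and the block by description number. A check of GC content was not run, as no genome sequence was used here.

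The scripts were tested on simulated data drawn from the means and library sizes of the real libraries, with 200 genes changed in each of 5 draws. With the spread of all 6 libraries, limma recovered 48.8% of 2-fold and 90.8% of 4-fold changes, and 6.68% of its calls were false. With the spread found without control replicate 1 it recovered 80.6% and 97%, with 7.79% false. In both cases 5 of 5 lowered lists were found and 0 unchanged lists were called. Each simulated gene was drawn independently of the others. The list result therefore does not show how camera with the preset correlation behaves when the genes of a list vary together. Figures were drawn with matplotlib 3.10.9.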

Results

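RNA was sequenced from CD8+ T cell preparations enriched out of tumours grown from E0771, a mammary carcinoma line of the C57BL/6 mouse strain. Mice bearing these tumours received an antibody against CD73 every 3 days or served as controls, and each group had 3 libraries. CD73 is the cell-surface ecto-5'-nucleotidase encoded by Nt5e, which forms adenosine from AMP outside cells, and adenosine acts on T cells through the receptor encoded by Adora2a. The comparison asks which transcripts differed in these tumour preparations when CD73 was targeted. The other 19 of the 25 samples of the series are RNA and chromatin accessibility libraries of spleen CD8+ T cells kept in culture for 7 days, in part with SCH58261, an antagonist of that receptor, and were not analysed here.

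Control replicates 1, 2 and 3 held 12809666, 10180624 and 17161679 recovered reads in genes, and anti-CD73 replicates 1, 2 and 3 held 13172235, 11618374 and 11997759. Between 15695 and 16596 genes had at least 1 read per library. The labels number the replicates without tying them to separate animals, so the p-values measure the spread between these samples, which may in part be technical.

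Transcripts of T cells were scarce in all 6 libraries. The 14 measured genes of the T cell receptor and CD8 identity list together took 0.00656, 0.00178 and 0.00224% of the reads of control replicates 1, 2 and 3, and 0.00657, 0.00577 and 0.0033% of those of anti-CD73 replicates 1, 2 and 3. Cd8a, the alpha chain of the CD8 co-receptor, stood at 122, 7.60 and 24.7 normalized counts in the controls and at 90.2, 82.6 and 35.0 after anti-CD73, and the value of 7.60 came from 6 reads (95% Poisson interval 2.20 to 13.1, which covers counting error only). Some genes of other cells were far more abundant. Krt8, a keratin of simple epithelia, lay between 1856 and 4559 normalized counts and Lyz2, the lysozyme of macrophages and granulocytes, between 973 and 4215. Other epithelial genes were about as scarce as Cd8a, with the keratin gene Krt18 between 37.0 and 112 and Epcam between 4.11 and 9.14. Haemoglobin transcripts, from red blood cells, took 0.232, 1.75 and 1.76% of the reads of the controls and 0.632, 0.981 and 0.263% of those of the anti-CD73 libraries. The preparations may thus be poorly enriched or hold whole tumour, which was not tested, and the fold changes below describe this mixed material rather than CD8+ T cells alone.

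**Figure D1:**
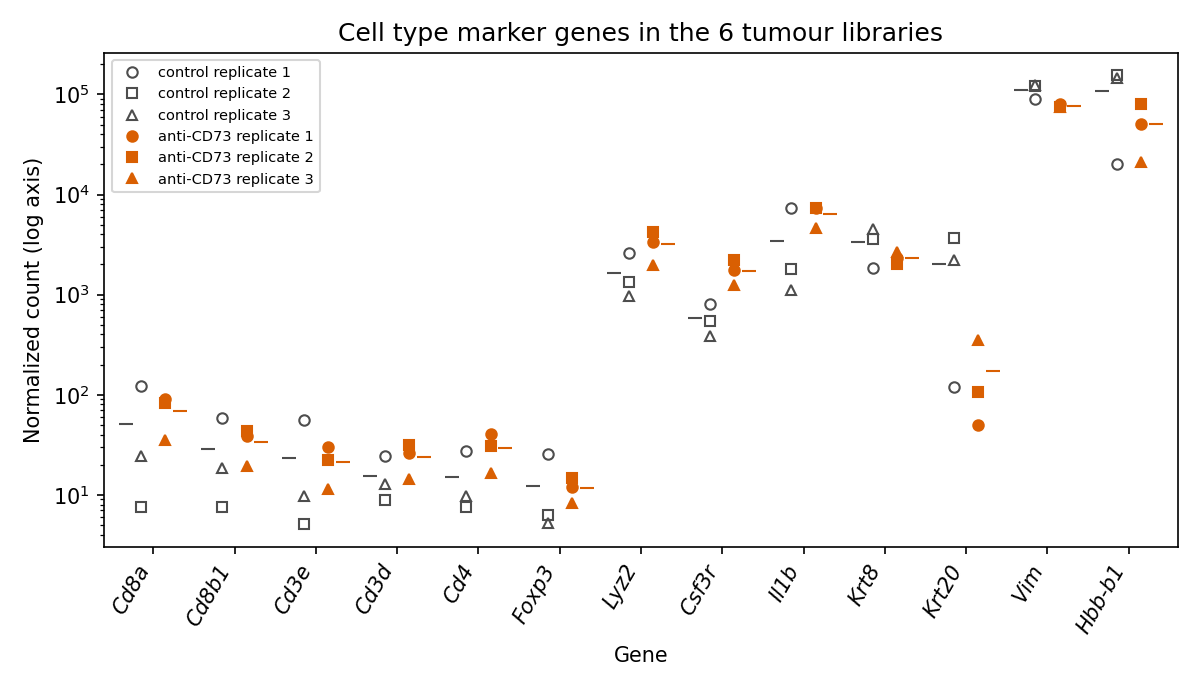
Normalized counts (log axis) of 13 marker genes in each of the 6 libraries, with open grey symbols for control, filled orange symbols for anti-CD73 and short horizontal lines for the group means. Cd8a lay between 7.60 and 122 in all libraries, while Vim, which many cell types express, lay between 74831 and 123008, and control replicate 1 sat nearer the anti-CD73 libraries than the other 2 controls for Lyz2, Il1b, Krt20 and Hbb-b1.

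Control replicate 1 stood apart from control replicates 2 and 3. Across the tested genes, the SD of its log2 difference from the mean of those 2 was 0.75, against 0.35 for the difference between them. The 14 T cell receptor and CD8 identity genes all lay above their level in the other controls, by 1.97 in the median on the log2 scale, and the 14 macrophage genes by 0.64 in the median. The 7 erythroid genes lay below it, by -3.08 in the median. The dendritic cell (1.30), adenosine metabolism (0.58) and endothelial lists (0.41) also lay above the other controls in the median, and glycolysis lay below (-0.41). On the first principal component, which held 52.7% of the variance, control replicate 1 scored -33.2, the other controls 37.7 and 43.8, and anti-CD73 replicates 1, 2 and 3 scored -20.8, -25.5 and -2.02.

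After anti-CD73, genes of cholesterol synthesis were lower as a group and genes of the type I interferon response, of macrophages and of neutrophils were higher (n = 3 libraries per group), by camera's competitive test with its preset correlation of 0.01. Of the 28 lists tested, 9 passed at an adjusted p of 0.05 in this test, and 0 passed with an estimated correlation. All 15 cholesterol synthesis genes lay lower, with a median log2 fold change of -0.65 (a fold of 0.635). All 19 interferon response genes lay higher, with a median of 0.52, as did all 14 macrophage genes, with a median of 0.70. Of the 9 tested neutrophil genes, 7 lay higher, with a median of 0.89.

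No single gene passed the test over all 12262 genes. By limma, 0 genes had an adjusted p under 0.05 (smallest 0.141), while 1902 genes, 15.5% of those tested, had an unadjusted p under 0.05, of which 1066 were higher and 836 lower after anti-CD73. The quasi-likelihood test of edgeR on recovered reads also called 0 genes and had 1868 at an unadjusted p under 0.05, whereas DESeq2 on the same reads called 542, of which 329 were higher and 213 lower. The values of the 2 groups did not overlap for 2880 genes, or 23.5%. The average over the 10 possible splits of the libraries is 10%, but a single split can lie away from it, as genes vary together. Without control replicate 1, limma called 2724 genes, of which 1465 were higher and 1259 lower, and edgeR called 2703 and DESeq2 2620. Leaving out any other single library kept both limma and edgeR at 0 calls, while DESeq2 fell to 42 calls without anti-CD73 replicate 2. Values without control replicate 1 are therefore given beside many of the main ones below, a choice that followed from these data. The test with all 6 libraries remains the main one. For the lists that gained a call without control replicate 1, that control lay on the anti-CD73 side of the other 2 in the median. With erythroid genes left out and the libraries rescaled to equal totals, 70.6% of the genes at an unadjusted p under 0.05 were higher, against 56.0% as deposited. That rescaling replaced the DESeq size factors and moved the median log2 fold change of all genes to 0.065. The larger share of higher genes may thus come from the scaling.

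**Figure D2:**
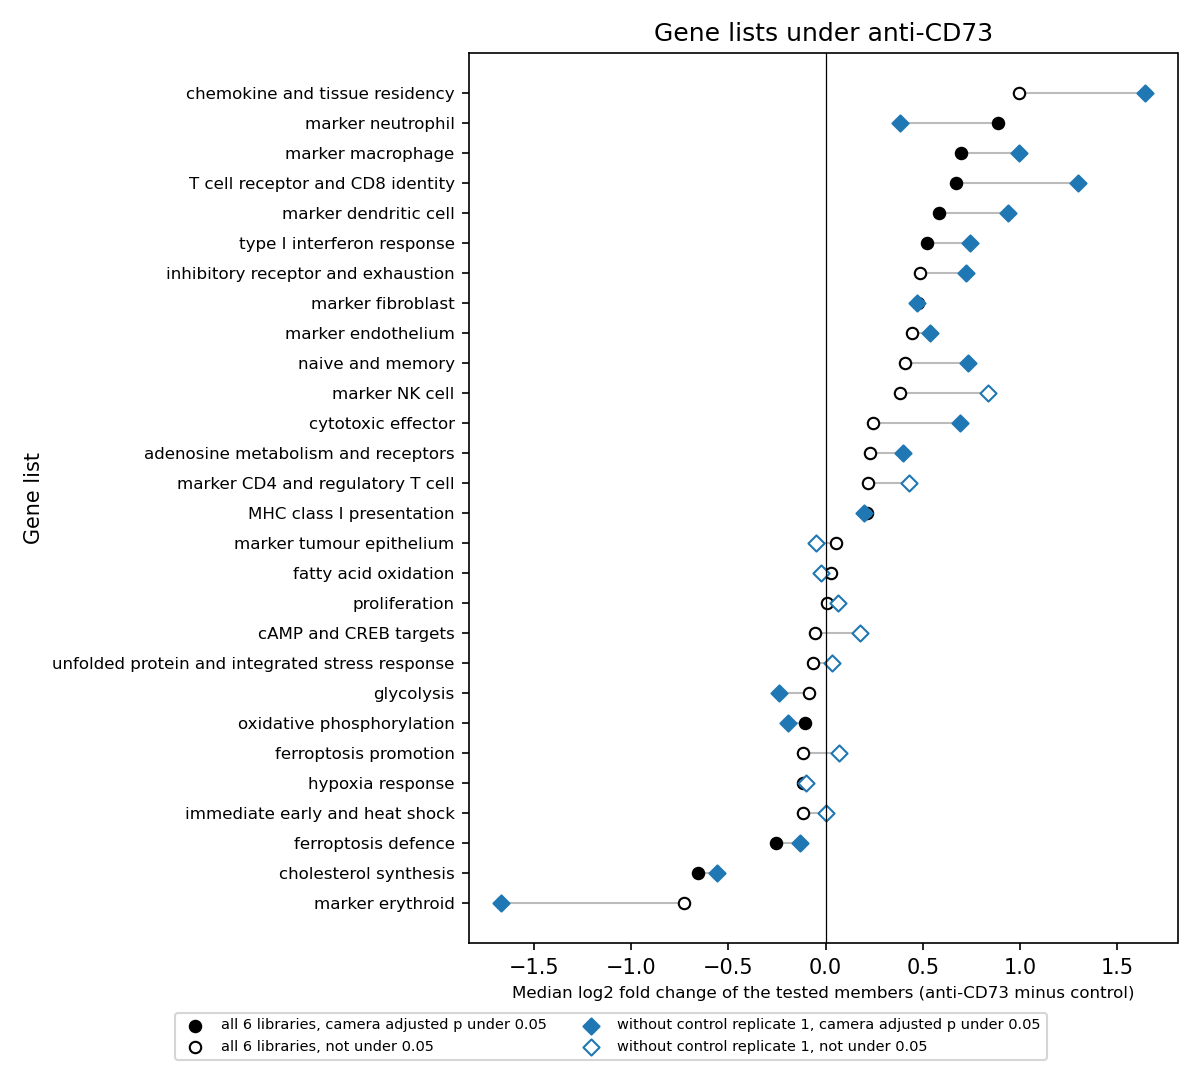
Median log2 fold change (anti-CD73 minus control) of the tested members of each of the 28 gene lists, with circles for all 6 libraries and diamonds without control replicate 1, filled where camera's adjusted p with the preset correlation was under 0.05. With all 6 libraries 9 lists are filled and without control replicate 1 there are 18, and the cholesterol synthesis list lay at -0.65 and -0.56.

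Cholesterol synthesis genes gave the smallest p of any list with the preset correlation and all 6 libraries, but not with an estimated correlation or without control replicate 1 (camera adjusted p = 2.1e-12; adjusted p = 0.45 with an estimated correlation). Of the 15 members, 11 were lower and 0 higher adjusted over the list alone, against 0 over all genes tested, and 13 of the 15 had groups that did not overlap. Hmgcs1, the synthase that makes HMG-CoA for this pathway (ENSMUSG00000093930; mm10 chromosome 13, 119690351 to 119708260), stood at 2676 ± 479 normalized counts in controls and 1045 ± 15.4 after anti-CD73 (SD, n = 3), a log2 fold change of -1.34 with a standard error of 0.15. Cyp51, the lanosterol demethylase, went from 1223 ± 373 to 483 ± 4.25 (log2 fold change -1.29, SE 0.22). Insig1, which holds the sterol sensor of this pathway in the endoplasmic reticulum, lay lower by a log2 fold change of -1.16 (SE 0.22). Srebf2 (-0.30), Dhcr7 (-0.27), Idi1 (-0.75) and Mvd (-0.29) did not pass adjusted over the list alone. The list's median without control replicate 1 was -0.56 and 13 members were lower over all genes tested.

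**Figure D3:**
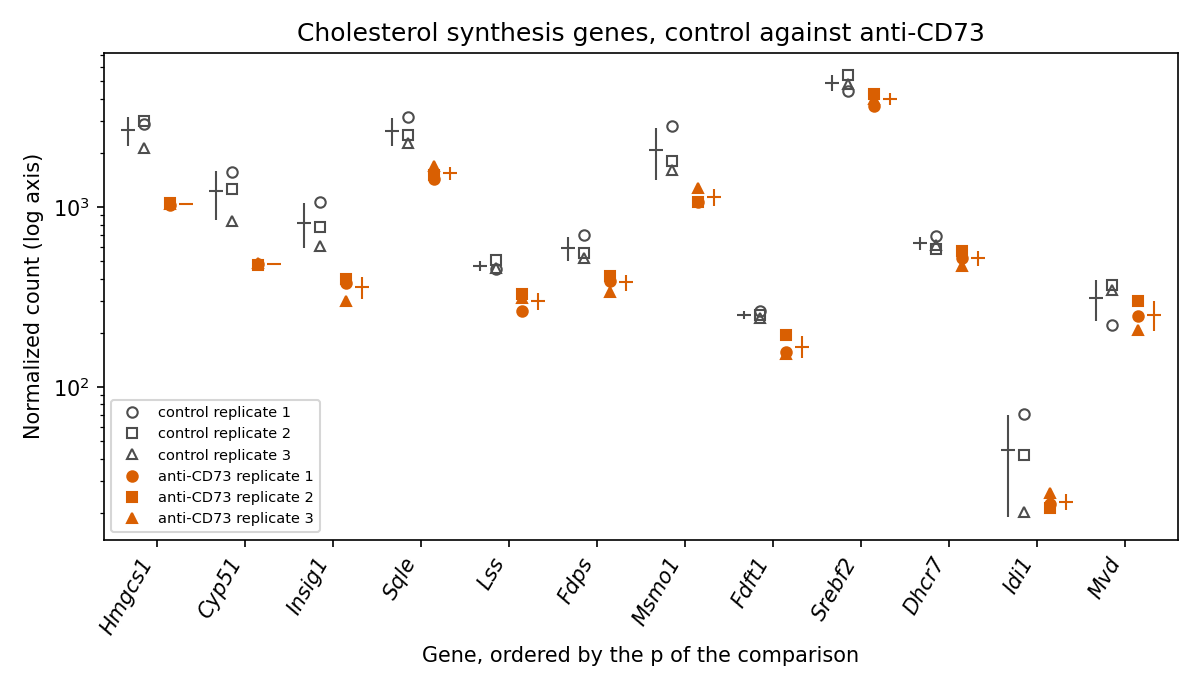
Normalized counts (log axis) of 12 of the 15 cholesterol synthesis genes in each library, with open grey symbols for control, filled orange symbols for anti-CD73, and horizontal ticks with vertical bars for the mean ± SD of the 3 libraries of each group. The groups did not overlap for 10 of these 12 genes, and Hmgcs1 stood at 2127 or more in each control and at 1061 or less after anti-CD73.

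Genes that defend cells against ferroptosis, the iron-dependent death by lipid peroxidation, were lower as a group (16 of 23 lower, median -0.25, camera adjusted p = 0.00102; adjusted p = 0.405 with an estimated correlation). Of these, 5 were lower and 0 higher adjusted over the list alone, against 0 over all genes tested. They were Nqo1 (log2 fold change -1.63, SE 0.25), Gclc (-0.63, SE 0.16), Gclm (-0.63, SE 0.18), Txn1 (-0.52, SE 0.11) and Prdx6 (-0.41, SE 0.11), which encode a quinone reductase, the 2 subunits of the enzyme that starts glutathione synthesis, a thioredoxin and a peroxiredoxin. Nqo1 stood at 157 ± 45.8 normalized counts in controls and 49.0 ± 7.69 after anti-CD73 (SD, n = 3). Gpx4, the phospholipid hydroperoxidase at the centre of this defence, had -0.36 (SE 0.28, adjusted p = 0.57), the cystine transporter gene Slc7a11 0.28 (SE 0.59, adjusted p = 0.854), Aifm2 0.15 (SE 0.27, adjusted p = 0.831) and the ferritin gene Fth1 -0.25 (SE 0.12, adjusted p = 0.376). The macrophage and neutrophil lists had medians of 0.70 and 0.89 in the same comparison (adjusted p = 0.622 and 0.591 with an estimated correlation). With the macrophage level as a covariate, a test chosen after the direction of the lists was known, the ferroptosis defence median was -0.39 (camera unadjusted p = 0.000131, and 0.0243 with an estimated correlation). Fits with this covariate, here and below, lean on control replicate 1, the only control whose macrophage level reached the anti-CD73 range. The list's median without control replicate 1 was -0.13, Gpx4 had -0.69 (adjusted p = 0.00588) and Slc7a11 1.04 (adjusted p = 0.00808). The ferroptosis promotion list had 12 of 19 members lower (median -0.11, mean 0.01, camera direction lower, adjusted p = 0.551) and 0 members past adjustment over the list alone or over all genes. In it, Alox5, a lipoxygenase of myeloid cells, had 1.19 (SE 0.32), Acsl4 -0.03 (SE 0.28, adjusted p = 0.973) and the transferrin receptor gene Tfrc -0.34 (SE 0.33, adjusted p = 0.662).

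Genes of oxidative phosphorylation were slightly lower as a group (21 of 24 lower, median -0.11, camera adjusted p = 0.00239; adjusted p = 0.622 with an estimated correlation). No member passed adjusted over the list alone (0 of 24), as over all genes tested. The members with the smallest p were Sdhc of complex II (-0.33, SE 0.10) and the complex I genes Ndufa9 (-0.30, SE 0.11) and Ndufa4 (-0.30, SE 0.12). Quantile normalization ended this call with a similar median (-0.097, adjusted p = 0.0544), erythroid genes left out with libraries rescaled gave -0.046 (adjusted p = 0.0063). With each library left out in turn the median ranged from -0.19 (without control replicate 1) to -0.089 (without anti-CD73 replicate 2). With the macrophage level as a covariate, a test chosen after the direction of the lists was known, the median was -0.16 and camera's unadjusted p went from 0.000511 to 0.149.

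Macrophage genes were higher as a group (camera adjusted p = 7.16e-05; adjusted p = 0.622 with an estimated correlation), and so were neutrophil genes (camera adjusted p = 0.000504; adjusted p = 0.591 with an estimated correlation). Of the 14 macrophage members, 3 were higher adjusted over the list alone, among them the integrin gene Itgam (log2 fold change 1.08, SE 0.29) and the Fc receptor gene Fcgr3 (0.88, SE 0.26), against 0 over all genes tested. For neutrophils, 4 of 9 were higher adjusted over the list alone, again against 0 over all genes. Those 4 were the chemokine receptor gene Cxcr2 (1.30, SE 0.18), the G-CSF receptor gene Csf3r (1.61, SE 0.30), S100a9 (0.89, SE 0.21) and the gelatinase gene Mmp9 (1.00, SE 0.28). The neutrophil members Ly6g (-0.035, SE 0.36) and Ngp (-0.0017, SE 0.85) did not lie higher, and S100a8 had 0.40 (SE 0.29). Csf3r stood at 580 ± 216 normalized counts in controls and 1740 ± 471 after anti-CD73 (SD, n = 3). Macrophage genes took 0.154, 0.126 and 0.0952% of the reads of the controls and 0.213, 0.248 and 0.154% of those after anti-CD73. The medians with each library left out in turn ranged from 0.45 (without control replicate 3) to 1.00 (without control replicate 1) for macrophages and from 0.39 (without control replicate 1) to 1.13 (without anti-CD73 replicate 3) for neutrophils.

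Dendritic cell genes were higher as a group (9 of 9, median 0.58, camera adjusted p = 0.0141; adjusted p = 0.622 with an estimated correlation), with 0 past adjustment over all genes or adjusted over the list alone. The integrin gene Itgax had 1.85 (SE 0.71) and the class II genes H2-Ab1 1.65 (SE 0.68) and Cd74 1.52 (SE 0.74). The smallest changes were those of Zbtb46 (0.31, SE 0.25), Ccl22 (0.39, SE 0.52) and Clec9a (0.45, SE 0.44). Control means of Ccl22 and Clec9a were only 10.8 and 9.65 normalized counts. The list's median turned to -0.054 with the macrophage level as a covariate, a test chosen after the direction of the lists was known. That fit leans on control replicate 1. Leaving out control replicate 2 (median 0.81, adjusted p = 0.0604), control replicate 3 (0.68, 0.125) or anti-CD73 replicate 1 (0.60, 0.0537) ended this call, and the median was 0.94 without control replicate 1 (adjusted p = 0.000468), 1.13 without anti-CD73 replicate 3 (0.00419) and 1.41 over the 6 members with a mean of at least 50 (0.0107). Fibroblast genes were higher as a group (8 of 11, median 0.48, camera adjusted p = 0.0096; adjusted p = 0.622 with an estimated correlation), a call lost without control replicate 3 (median 0.28, adjusted p = 0.172). In this list 2 members were higher adjusted over the list alone, against 0 over all genes tested. They were the fibronectin gene Fn1 (1.45, SE 0.23) and the smooth muscle actin gene Acta2 (0.77, SE 0.18). The fibroblast members Postn (-0.66, SE 0.32), Fap (-0.02, SE 0.47) and Dcn (-0.01, SE 0.42) did not lie higher, and Pdgfra had 0.09 (SE 0.13). All 6 endothelial genes lay higher without passing (median 0.45, camera adjusted p = 0.0999), with 0 members past adjustment over all genes or adjusted over the list alone and Pecam1 at 1.70 (SE 0.53). That list passed without control replicate 1 (0.54, adjusted p = 0.0228, or 0.406 with an estimated correlation) and without anti-CD73 replicate 3 (0.57, 0.0395).

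Interferon response genes were higher as a group (camera adjusted p = 1.95e-06; adjusted p = 0.622 with an estimated correlation). Of the 19 members, 1 was higher adjusted over the list alone, against 0 over all genes tested. That member was Irf7, the interferon regulatory factor that amplifies the response, at 3717 ± 143 normalized counts in controls and 7068 ± 1820 after anti-CD73 (SD, n = 3; log2 fold change 0.89, SE 0.19). The antiviral genes Mx1 (1.42, SE 0.45), Ifit3 (1.05, SE 0.31) and Isg15 (0.71, SE 0.22) did not pass on their own. The MHC class I presentation list did not pass (8 of 12 higher, median 0.21, camera adjusted p = 0.13, with 0 members past adjustment over all genes or adjusted over the list alone), with H2-K1 at 0.41 (SE 0.12). The interferon median without control replicate 1 was 0.74. The class I list then passed (0.20, adjusted p = 0.0349), as it did without anti-CD73 replicate 3 (0.30, 0.0238) and with quantile normalization (0.29, 0.0205). Control replicate 1 itself lay above the other 2 controls, by a median of 0.71 for interferon genes (17 of 19 higher) and 0.16 for class I genes. An estimated correlation ended the class I call without control replicate 1 (camera adjusted p = 0.623). The class I median was 0.13 without control replicate 2. The macrophage genes given above moved in the same direction as the interferon genes.

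T cell receptor and CD8 identity genes were higher as a group (14 of 14, median 0.67, camera adjusted p = 0.0155; adjusted p = 0.874 with an estimated correlation). The macrophage, dendritic cell and neutrophil lists also lay higher (medians of 0.70, 0.58 and 0.89). With the macrophage level as a covariate, a test chosen after the direction of the lists was known, the T cell identity median turned to -0.43. That fit leans on control replicate 1, in which the T cell identity genes lay 1.97 above the other controls in the median. Of the 14 members, 0 passed adjusted over the list alone, as over all genes tested. The signalling kinase gene Lck had a log2 fold change of 0.69 (SE 0.27), Cd8a 1.11 (SE 0.90, adjusted p = 0.591), Cd8b1 0.62 (SE 0.69, adjusted p = 0.707) and Cd3e 0.42 (SE 0.82, adjusted p = 0.842). This call was lost without control replicate 2 (median 0.35, adjusted p = 0.399), control replicate 3 (0.54, 0.185) or anti-CD73 replicate 1 (0.47, 0.141) and with quantile normalization (0.39, 0.0587). Without control replicate 1 the median was 1.30 (adjusted p = 5.34e-05) and Cd8a had 2.13 (adjusted p = 0.0225).

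The cytotoxic effector list did not pass (14 of 20 higher, median 0.24, camera adjusted p = 0.729), with 0 members past adjustment over all genes or adjusted over the list alone. The granzyme gene Gzmb had a log2 fold change of 0.05 (SE 0.47, adjusted p = 0.974), the perforin gene Prf1 0.28 (SE 0.30, adjusted p = 0.689), Ifng -0.31 (SE 0.90, adjusted p = 0.902) and Tnf 0.26 (SE 0.49, adjusted p = 0.838). The inhibitory receptor and exhaustion list did not pass (11 of 16 higher, median 0.48, camera adjusted p = 0.13). Adjusted over the list alone, Nr4a1 (0.71, SE 0.19) and Batf (0.79, SE 0.21) were higher and Nr4a2 lower (-0.97, SE 0.22), against 0 members over all genes tested. The checkpoint genes Pdcd1 (0.74, SE 0.55, adjusted p = 0.56), Havcr2 (0.47, SE 0.18, adjusted p = 0.284) and Lag3 (0.57, SE 0.48, adjusted p = 0.613) did not pass, and Tox, at 5.99 ± 6.24 and 9.85 ± 11.7 normalized counts (SD, n = 3), was below the minimum for testing. The naive and memory list (14 of 15 higher, median 0.41, camera adjusted p = 0.0574) and the chemokine and tissue residency list (9 of 12 higher, median 1.00, camera adjusted p = 0.0999) did not pass either, with 0 members past adjustment over all genes or adjusted over the list alone. Tcf7 had 0.41 (SE 0.23, adjusted p = 0.441), Il7r 0.56 (SE 0.68, adjusted p = 0.732) and Itga4 1.25 (SE 0.54). These 4 lists passed without control replicate 1, with medians of 0.69 (adjusted p = 0.0319), 0.72 (0.00131), 0.73 (0.00184) and 1.64 (0.000468), in the order given here. None of them passed there with an estimated correlation (camera adjusted p = 0.594 for cytotoxic effectors and 0.406 for the others). Control replicate 1 itself, an untreated library, lay above the other 2 controls by medians of 1.23, 1.21, 1.04 and 1.71, in the same order. Without anti-CD73 replicate 3 the exhaustion (0.70, adjusted p = 0.0294), naive and memory (0.49, 0.0217) and chemokine lists (adjusted p = 0.0354) passed. The exhaustion median fell to 0.14 and the chemokine median to 0.60 without control replicate 2, and the naive and memory median to 0.20 without control replicate 3. The cytotoxic list turned in camera's direction without control replicate 2 (median -0.13), control replicate 3 (-0.018) or anti-CD73 replicate 1 (0.094). A block by title number also called the naive and memory (adjusted p = 0.0207) and chemokine lists (0.0119), and no filter called the former (0.0467).

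Genes of adenosine metabolism did not pass as a group (9 of 13 higher, median 0.23, camera adjusted p = 0.13), with 0 members past adjustment over all genes or adjusted over the list alone. Nt5e, the gene of the antibody's target (ENSMUSG00000032420; mm10 chromosome 9, 88327609 to 88372089), stood at 71.8 ± 18.7 normalized counts in controls and 76.2 ± 21.8 after anti-CD73 (SD, n = 3), a log2 fold change of 0.08 (SE 0.29, adjusted p = 0.922). Adora2a stood at 37.9 ± 15.6 and 113 ± 43.0 with groups that did not overlap (1.56, SE 0.42, adjusted p = 0.178), Adora2b had 0.23 (SE 0.16, adjusted p = 0.548) and Entpd1, which encodes the ectonucleotidase CD39, had 1.04 (SE 0.40, adjusted p = 0.284). DESeq2 called Adora2a higher (adjusted p = 0.012). Without control replicate 1 this list passed (median 0.40, adjusted p = 0.00782, or 0.406 with an estimated correlation) and Adora2a had 1.84 (adjusted p = 0.0108). Without control replicate 3 the median fell to 0.11. The list of cAMP and CREB targets, which lie downstream of the Adora2a receptor, did not pass (9 of 15 lower, median -0.06, camera adjusted p = 0.647). Adjusted over the list alone, Fosb (-0.89, SE 0.18) and Nr4a2 (-0.97, SE 0.22) were lower and Nr4a1 (0.71, SE 0.19) was higher, against 0 over all genes tested.

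The proliferation list did not pass (13 of 24 higher, median 0.01, mean -0.02, camera direction lower, adjusted p = 0.792), with 0 members past adjustment over all genes or adjusted over the list alone, and Mki67 had 0.12 (SE 0.11, adjusted p = 0.621). The hypoxia list did not pass (8 of 13 lower, median -0.12, camera adjusted p = 0.273; -0.22 to -0.079 with each library left out in turn). Adjusted over the list alone, the collagen prolyl hydroxylase gene P4ha2 was higher (0.68, SE 0.13) and Egln3 (-0.51, SE 0.13), Kdm3a (-0.42, SE 0.12) and Adm (-0.69, SE 0.21) were lower, against 0 over all genes tested. Glycolysis (12 of 15 lower, median -0.08, camera adjusted p = 0.283) had 0 members past adjustment over all genes or adjusted over the list alone. It passed without control replicate 1 (-0.24, adjusted p = 0.00782, or 0.406 with an estimated correlation). Its median was -0.025 without control replicate 3. Reads of its member Gapdh (-0.33, SE 0.10) may be shared with pseudogenes, so its level is uncertain. Fatty acid oxidation (7 of 12 higher, median 0.03, camera adjusted p = 0.744) had 1 member higher adjusted over the list alone, the carnitine carrier gene Slc25a20 (0.76, SE 0.16). The unfolded protein and integrated stress response list (6 of 11 lower, median -0.07, camera adjusted p = 0.975) also had 1 higher, the endoplasmic reticulum gene Sdf2l1 (0.69, SE 0.13). The immediate early and heat shock list (10 of 16 lower, median -0.12, mean 0.07, camera direction lower, adjusted p = 0.741) had 1 lower adjusted over the list alone, Fosb. Over all genes tested, none of these 3 genes passed.

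Among the remaining markers of other cells, 7 of 7 erythroid genes lay lower without passing (median -0.73, camera adjusted p = 0.274). They passed without control replicate 1 (-1.67, adjusted p = 0.000228, or 0.406 with an estimated correlation). Their median was -0.20 without anti-CD73 replicate 3. The near-identical genes Hba-a1 and Hba-a2 in that list share reads and are uncertain on their own. The list of CD4 and regulatory T cells had 5 of 7 members higher (median 0.22, camera adjusted p = 0.574; -0.048 without control replicate 2 to 0.43 without control replicate 1), with Cd4 at 1.05 (SE 0.55, adjusted p = 0.403). The tumour epithelium list had 4 of 6 higher (median 0.05, camera adjusted p = 0.741), with Krt8 at -0.43 (SE 0.31) and Krt19 at 1.83 (SE 1.15). In these 3 lists 0 members passed over all genes or adjusted over the list alone. The NK cell list had 4 of 6 higher (median 0.38, camera adjusted p = 0.741). Adjusted over the list alone, its member Tyrobp, an adaptor gene also expressed by myeloid cells, was higher (0.98, SE 0.26) and the receptor gene Klra4 lower (-0.83, SE 0.25), against 0 over all genes tested. Markers of B and plasma cells (3 tested members, median 0.39), adipocytes (1 member, -0.40), mammary secretory cells (1 member, -0.70) and skeletal muscle (4 members, 0.35) had too few tested members for a list test.

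The 8 genes with the smallest p in each direction did not pass over all genes tested (limma adjusted p = 0.141 for each), and for each of the 16 the groups did not overlap. The higher genes were Smox (log2 fold change 0.93, SE 0.12), a spermine oxidase; Itga7 (1.48, SE 0.20), a laminin-binding integrin; Cxcr2 (1.30, SE 0.18); the complement gene C3 (1.49, SE 0.21); the homeobox gene Hlx (1.48, SE 0.22); Dgat1 (0.84, SE 0.13), which makes triglycerides; Fn1 (1.45, SE 0.23); and the adaptor gene Sh2b2 (0.71, SE 0.12). Smox stood at 2518 ± 173 normalized counts in controls and 4819 ± 511 after anti-CD73 (SD, n = 3). The lower genes were Hmgcs1 (-1.34, SE 0.15), the caveolar gene Sdpr (-1.09, SE 0.12), the thiamine transporter gene Slc19a2 (-1.01, SE 0.12), Pthlh (-1.49, SE 0.20), which encodes parathyroid hormone-related protein, the co-chaperone gene Dnajb4 (-0.77, SE 0.10), Tiparp (-0.74, SE 0.11), a target of the aryl hydrocarbon receptor, the syndecan gene Sdc2 (-0.69, SE 0.10) and Arl4a (-0.86, SE 0.13). DESeq2 called all 16, with adjusted p from 6.2e-10 for Hmgcs1 to 0.00019 for Sh2b2. Without control replicate 1, limma called all 16, with adjusted p from 0.000935 for Slc19a2 to 0.00392 for Fn1.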

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

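Tests chosen only after the data were seen are those with erythroid genes left out, the estimated correlation without control replicate 1, edgeR and DESeq2 with libraries left out and, for the lists, a pseudocount of 0.5, a mean of at least 50, quantile normalization, robust empirical Bayes and the block by description number; the cause of a change was not tested unless stated. Pseudocounts of 0.5 and 8, no filter, a mean of at least 50, TMM, quantile normalization, robust empirical Bayes and edgeR left 0 genes called, while DESeq2 called 542 (329 higher, 213 lower). With an estimated correlation 0 lists passed, with all 6 libraries or without control replicate 1. Over all alternatives of the 28 lists, 409 values kept direction and side of the threshold, 27 lost a call, 26 gained one and 36 changed direction. For the 39 single genes tested, these counts were 598, 0, 66 and 34. As no gene passed in the main test, none could lose a call.

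Single libraries were left out in turn. Called genes then ranged from 0 to 2724 (higher 0 to 1465, lower 0 to 1259), genes at an unadjusted p under 0.05 from 854 to 4461, edgeR calls from 0 to 2703, DESeq2 calls from 42 to 2620 and lists from 6 to 18, with the highest value without control replicate 1 in each case. Lists that changed direction had medians from -0.13 to 0.69 for cytotoxic effectors, -0.076 to 0.062 for proliferation, -0.18 to 0.18 for cAMP and CREB targets, -0.22 to 0.068 for ferroptosis promotion, -0.023 to 0.046 for fatty acid oxidation, -0.20 to 0.032 for the unfolded protein response, -0.16 to 0.034 for immediate early genes, 0.022 to 0.83 for NK cells and -0.048 to 0.15 for tumour epithelium. Direction here is that of camera, which can differ from the sign of the median. Genes that changed direction had log2 fold changes from -0.14 to 0.27 for Nt5e, -0.050 to 1.35 for Cd8b1, -0.26 to 1.36 for Cd3e, -0.33 to 0.55 for Gzmb, -0.88 to 0.72 for Ifng, -0.075 to 0.90 for Tnf, -0.15 to 1.40 for Il7r, -0.30 to 1.04 for Slc7a11, -0.13 to 0.38 for Aifm2, -0.25 to 0.30 for Acsl4 and -0.57 to 0.087 for Tfrc. The T cell identity (0.35 to 1.30), dendritic cell and fibroblast lists lost their call without at least 1 library, and 9 lists gained one: cytotoxic effectors, exhaustion, naive and memory, chemokines, MHC class I, adenosine metabolism, glycolysis, endothelium and erythroid. Of the 9 lists called with all libraries, 9 were called without control replicate 1, 7 without control replicate 2, 6 without control replicate 3, 7 without anti-CD73 replicate 1 and 9 each without anti-CD73 replicates 2 and 3.

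Quantile normalization turned the direction of proliferation (0.033), glycolysis (-0.018), the unfolded protein response (0.0059), immediate early genes (-0.057), Nt5e (-0.11), Gzmb (-0.0044) and Fth1 (0.037). A mean of at least 50 turned the unfolded protein response (-0.065). Without erythroid genes, proliferation (0.071), the unfolded protein response (-0.0042) and Acsl4 (0.031) turned, and the median of all genes was 0.065. On recovered reads Cd3e, Gzmb, Tnf and Slc7a11 turned, to -0.13, -0.050, -0.026 and -0.13 with edgeR and to -0.16, -0.076, -0.053 and -0.16 with DESeq2. With an estimated correlation without control replicate 1, proliferation (0.062), cAMP and CREB targets (0.18), ferroptosis promotion (0.068), fatty acid oxidation (-0.023), the unfolded protein response (0.032) and tumour epithelium (-0.048) turned.

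The replicate numbers share no stated origin, and libraries of the same title number did not all deviate together (correlations of 0.19, -0.10 and 0.26), so they were not taken as pairs. A block by title number gave 0 called genes, 1834 at an unadjusted p under 0.05 and 11 lists, with chemokines and naive and memory gained. A block by description number gave 1780 genes (1096 higher, 684 lower), 3561 at an unadjusted p under 0.05 and 17 lists. In that block design control replicate 1 and anti-CD73 replicate 2 share their numbers with no other library and so add nothing to the comparison, as if left out. It turned proliferation (0.046), cAMP and CREB targets (0.18), ferroptosis promotion (0.042), fatty acid oxidation (-0.013), the unfolded protein response (0.049), tumour epithelium (0.0062), Ifng (0.51), Aifm2 (-0.22), Acsl4 (0.24) and Tfrc (0.16).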

Other observations

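The lists of further cholesterol pathway genes, fatty acid synthesis and sterol efflux, the values of Krt20 and Cxcl1, the cholesterol level of control replicate 1, and the tests of read depth, haemoglobin reads, gene length, another mix of cells and proliferation were chosen after the results they bear on were seen, and the tests with the macrophage level as a covariate were chosen once the direction of the lists was known but before their own values were.

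Genes of the cholesterol pathway outside the fixed list were also lower as a group after anti-CD73 (11 of 11, median log2 fold change -0.46, camera adjusted p = 7.26e-05 over 3 added lists; adjusted p = 0.116 with an estimated correlation). Adjusted over the list alone, 4 were lower, against 0 over all genes tested: the sterol carrier gene Stard4 (-0.89, SE 0.20), the sterol enzyme genes Hsd17b7 (-0.96, SE 0.23) and Nsdhl (-0.56, SE 0.17), and Acat2 (-0.68, SE 0.19), which makes acetoacetyl-CoA. Genes of fatty acid synthesis did not pass (7 of 10 lower, median -0.19, camera adjusted p = 0.112, with 0 past adjustment over the list or over all genes), and Fasn, the fatty acid synthase gene, had 0.04 (SE 0.12) and Srebf1 0.16 (SE 0.12). Whether the 2 lists differed from each other was not tested. Genes of sterol efflux and liver X receptor targets did not pass either (7 of 7 higher, median 0.13, camera adjusted p = 0.0878, with 0 past adjustment over the list or over all genes), with Nr1h3 at 1.37 (SE 0.53) and Abca1 at 0.79 (SE 0.39). Without control replicate 1 the medians were -0.40 (adjusted p = 0.00233), -0.07 (0.942) and 0.20 (0.0257).

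Krt20, a keratin of differentiated epithelium, stood at 119, 3654 and 2235 normalized counts in control replicates 1, 2 and 3 and at 50.2, 106 and 356 in anti-CD73 replicates 1, 2 and 3 (log2 fold change -2.99, limma adjusted p = 0.323; -4.52 and 0.00309 without control replicate 1). The chemokine gene Cxcl1 stood at 49357, 15350 and 12168 in the controls and at 13462, 12464 and 19084 after anti-CD73 (log2 fold change -0.51, adjusted p = 0.656; 0.11 and 0.693 without control replicate 1).

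The 6 libraries split into 10 pairs of 3 against 3, so no share of splits can lie under 0.05. The real split gave 0 limma calls and the highest other 0, so 10 of 10 splits gave as many. It gave 1902 genes at an unadjusted p under 0.05 and 542 DESeq2 calls, and in each case 2 of the 10 splits gave as many, the highest other being 2096 and 761. It gave 9 lists, 6 of the 10 splits gave as many, and the highest other gave 18. The split with these higher values sets control replicate 1 with anti-CD73 replicates 1 and 2 against the rest, which points to a structure of the samples that the groups do not give.

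Control replicate 1 stood apart from the other 2 controls. Its 12809666 reads lay inside the range of the other libraries, which argues against depth. Haemoglobin took 0.232% of its reads against 1.75 and 1.76%, a difference that could shift all other genes by a log2 value of 0.022, far less than the SD of 0.75 of its differences from the other controls, which argues against displaced reads. The differences rose with gene length, introns included (Spearman correlation 0.22 over 11810 genes), but their SD was 2.20 times that between the other controls before a trend on that length was removed and 2.18 times after, which argues against such a bias as the main cause; transcript length was not tested. Another mix of cells stays open: the 59 genes of the 6 fixed leukocyte lists lay 1.07 log2 units above the other controls in the median, with 83.1% higher, but the neutrophil list among them lay at -0.18 with 3 of 9 higher, and these values were seen before the test, so it could only have argued against this. Its cholesterol synthesis genes lay 0.37 above the other controls in the median, away from the anti-CD73 libraries. A difference between animals or tumours stays open and untested.

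The lower level of the cholesterol genes may reflect fewer tumour cells beside more myeloid cells, or fewer cycling cells, and both were tested. With the macrophage level as a covariate the list's median coefficient was -0.91, further from 0 than the -0.65 without it (camera p = 0.0217 with an estimated correlation, not adjusted). The macrophage level thus did not account for the lower list in this fit, but it does not measure tumour cells. Its mean log2 value was 10.1, 9.66 and 9.35 in control replicates 1, 2 and 3. After anti-CD73 it was 10.4, 10.7 and 9.97, a range that only control replicate 1 reached. The first explanation therefore stays open. The median of the proliferation list was 0.0097 (bootstrap interval -0.057 to 0.072), above the bootstrap interval of the cholesterol median (-0.77 to -0.59), which argues against the second. These intervals came from resampling the genes of each list and do not cover the spread between libraries. A response of the cells to anti-CD73 remains a hypothesis, and which cells carry it was not tested, since these libraries mix cell types.

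The higher level of the interferon genes may follow from more myeloid cells in the preparations after anti-CD73. With the macrophage level as a covariate, the list's median coefficient for anti-CD73 went from 0.52 to -0.050, as it would if this were so. The fit cannot decide this, as it leans on control replicate 1, the only control whose macrophage level reached the anti-CD73 range. Interferon genes of that control also lay 0.71 above the other 2 controls in the median, against 0.74 for the anti-CD73 libraries. The covariate itself lay higher after anti-CD73, so a response to the antibody that raised both cannot be excluded by this fit. The T cell identity list went from 0.67 to -0.43 and the neutrophil list from 0.89 to 0.59 in the same fit.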
